A study of Mus musculus with 17 samples.

How the data were processed

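RNA was measured in 17 libraries of macrophages sorted from mouse liver and adipose tissue. Per the submitters' processing notes, total RNA was amplified with a SMARTer kit and sequenced as single-end reads on a HiSeq 3000, reads were demultiplexed with bcl2fastq and aligned with STAR 2.0.4b, and the deposited gene counts were made with Subread featureCounts 1.4.5. The genome build and the annotation release were not stated, nor whether molecular identifiers were used or duplicates removed, so statements on depth cover counting error only. The deposited table gave Ensembl identifiers, symbols and biotypes without positions, and its values were whole counts in 40824 entries, 276 of them repeats of an identifier, which left 40548 genes.

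Groups were taken from the source given for each sample. They were standard diet Kupffer cells (STD KC, 3 libraries) and high fat, high sucrose diet Kupffer cells (HFD KC, 5). The others were Cx3cr1 reporter-positive liver macrophages (Cx3cr1pos HFD, 4) and adipose tissue macrophages (ATM HFD, 5). Library names and sort labels were taken from the sample titles. Names that begin with hf, hfd or std may mark batches, which the labels do not say. Within HFD KC the prefix coincides with the sort label, CD68 for hf and frac_neg for hfd. The STD KC libraries, all of them named std and the only ones so named, are labelled frac_neg. The ATM libraries are labelled frac_neg and the Cx3cr1pos libraries frac_pos.

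Genes with low counts were removed with filterByExpr, which left 15285. Counts were scaled with TMM factors, and a quasi-likelihood negative binomial model with 1 coefficient per group was fitted to the 17 libraries in edgeR 4.0.16 under R 4.3.3, followed by two-sided quasi-likelihood F-tests (glmQLFTest) and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05. Log2 CPM used a prior count of 2, means and SDs are of CPM, and the floor for a gene without counts was 3 counts per library. The common biological coefficient of variation was 0.297. Gene lists, 30 in number with 524 genes, were written before the data were examined, 2 of their symbols are not in the table, and they were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry. The lists passing with an estimated correlation were 2, 2, 3 and 3 in the 4 comparisons in the order of the report.

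The genes named were set by a rule made before the data were examined: the 10 largest rises and the 10 largest falls per comparison among genes past the threshold with a mean of at least 20 CPM in the higher group and no overlap between the libraries of the groups, unnamed models and pseudogenes left out, up to 4 members per list with the smallest adjusted p, and the 5 sort markers. The text names part of these genes, with preference for those whose call held without any single library. Trem2 and Clec4g in the first comparison, Cd207 and Mmp12 in the second, Mmp12 in the third and Folr2 and Cd163 in the fourth lie outside the rule and were chosen after their values were seen.

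On simulated data with 50 changed genes per fold, the test recovered 10, 36, 66 and 84% of genes changed 1.5, 2, 4 and 8 times in the first comparison with 1 false call, and 22, 48, 80 and 96% in the second with 6. In the third it recovered 20, 56, 80 and 84% with 5 false calls, and in the fourth 20, 46, 80 and 94% with 6.

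Libraries of HFD KC and Cx3cr1pos HFD that share a name were checked as pairs: the correlation across genes of the deviations from the group mean was 0.301 for hfd2, 0.174 for hf1, 0.166 for hf2 and 0.233 for hf3, each above that with any other name, though genes are not independent replicates. Alternatives set before the data were examined were DESeq2 1.42.0, RLE factors, no filter, only the groups compared, a prefix term, a replicate block, subsets by name or sort label and leaving out each library. Total counts in place of TMM, the counts of list members under every alternative, and the glycolysis list without Gapdh and Pgk1 were added after seeing the data. In the 17 libraries Gapdh stood at 7.02 to 13.7 CPM and Pgk1 at 6.04 to 15.6, and whether these counts measure the genes stays open, since reads shared with pseudogenes could not be traced.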

Results

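The series holds RNA sequencing of macrophages sorted from the liver and the adipose tissue of Cx3Cr1-GFP/WT mice on a C57BL/6 background, in which 1 copy of the chemokine receptor gene Cx3cr1 is replaced by a green fluorescent reporter. The mice ate standard chow (STD) or a high fat, high sucrose diet (HFD) for 16 weeks. The 17 libraries fall into 4 groups. STD KC (n = 3) and HFD KC (n = 5) are liver cells sorted as F4/80-high and TIM4-positive, the surface profile of resident Kupffer cells (KC), the macrophages of the liver sinusoids. Cx3cr1pos HFD (n = 4) are reporter-positive liver macrophages, and ATM HFD (n = 5) are adipose tissue macrophages sorted on F4/80 and CD64. The total count per library lay between 25.6 and 38.2 M counts, with group means of 32.9 ± 1.89 (SD) M in STD KC, 35.8 ± 2.06 in HFD KC, 31.8 ± 5.19 in Cx3cr1pos HFD and 31.3 ± 3.43 in ATM HFD. At this depth 3 counts correspond to 0.0785 to 0.117 CPM (counts scaled to the library total). Mitochondrial transcripts took 0.506 ± 0.142% of the counts in STD KC, 0.513 ± 0.110% in HFD KC, 0.362 ± 0.067% in Cx3cr1pos HFD and 0.916 ± 0.320% in ATM HFD.

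The groups lay apart on the first principal components. The first principal component of log2 CPM, 57.5% of the variance, set ATM apart from the liver cells, and the second, 12%, ordered the liver groups from STD KC through HFD KC to Cx3cr1pos HFD. By the correlation of log2 CPM across genes, which are not independent replicates, HFD KC hfd2 was closest to Cx3cr1pos HFD hfd2 (r = 0.973) and not to a library of its own group. Each of the other libraries was closest to one of its own group.

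**Figure D1:**
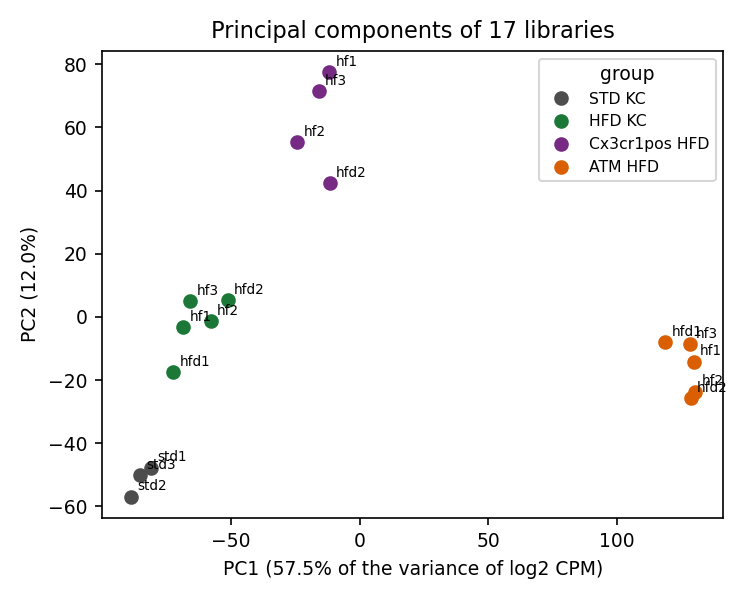
First against second principal component of log2 CPM for the 17 libraries, 1 point per library, coloured by group and marked with the library's name. The 5 ATM libraries lie apart on the first component (57.5% of the variance), and the liver groups lie apart on the second (12%).

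The genes behind the sort were read first, as a check of the labels and not as findings. Timd4, which encodes TIM4, stood at 1413 ± 167 CPM in STD KC and 1133 ± 469 in HFD KC against 35.7 ± 7.75 in Cx3cr1pos HFD and 5.76 ± 1.45 in ATM HFD. It was lowest of the HFD KC libraries in hfd2, 73.4% of the way from the STD KC mean to the Cx3cr1pos HFD mean. The other HFD KC libraries lay at -17.6 to 26.7% on that scale. Cx3cr1 stood at 398 ± 71.7 CPM in Cx3cr1pos HFD against 3.34 ± 0.668 in STD KC, 9.70 ± 4.97 in HFD KC and 17.3 ± 7.60 in ATM HFD. Adgre1, which encodes F4/80, stood at 4349 ± 320, 4952 ± 1182, 2755 ± 832 and 3291 ± 831 CPM in these groups in the order STD KC, HFD KC, Cx3cr1pos HFD and ATM HFD. In the same order Fcgr1, which encodes CD64, stood at 378 ± 19.3, 399 ± 67.9, 440 ± 35.0 and 244 ± 90.7 CPM, and Cd68, the name given to 3 HFD KC libraries as a sort label, at 2755 ± 356, 2408 ± 338, 2693 ± 88.8 and 3607 ± 229 CPM.

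The first comparison, HFD KC against STD KC, addresses the effect of the diet on TIM4-positive Kupffer cells. Genes of the lipid-associated macrophage list, a program of macrophages that handle lipid in obese tissue, were higher in HFD KC. Mmp12 (ENSMUSG00000049723), a macrophage elastase, rose from 49.9 ± 44.6 to 1156 ± 426 CPM, 23.1-fold (log2 fold change 4.53 ± 0.50 SE, adjusted p = 0.00014). The tetraspanins Cd63 (ENSMUSG00000025351) and Cd9 (ENSMUSG00000030342) rose from 9.17 ± 5.47 to 119 ± 59.7 CPM (3.70 ± 0.41, adjusted p = 0.00014) and from 36.9 ± 4.89 to 167 ± 27.9 CPM (2.17 ± 0.24, adjusted p = 0.00014). Cd207 (ENSMUSG00000034783), the C-type lectin langerin, fell from 918 ± 134 to 272 ± 113 CPM (log2 fold change -1.75 ± 0.25, adjusted p = 0.0011). For each of these genes every HFD KC library lay on one side of all 3 STD KC libraries. Without STD KC std1, whose Mmp12 level of 101 CPM was the highest of its group, the log2 fold changes of Mmp12 and Cd63 were 5.56 and 4.29.

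Of the 22 lipid-associated macrophage genes, 12 rose, none fell and 10 did not pass the test (17 rose when adjusted over the list alone; camera adjusted p = 2.7e-27, and 0.0088 with an estimated correlation). Anpep, an aminopeptidase, rose by 3.12 ± 0.40 on the log2 scale, and Gpnmb, a glycoprotein of lipid-laden macrophages, from 34.8 ± 40.5 to 527 ± 600 CPM (3.92 ± 0.87, adjusted p = 0.018; 5.52 without STD KC std1 and 2.91 without HFD KC hfd2). The lipid receptor Trem2, chosen after its values were seen, rose from 69.0 ± 7.72 to 197 ± 110 CPM (1.51 ± 0.32, adjusted p = 0.015). Of the 19 monocyte-derived cell genes 8 rose and none fell (12 rose adjusted over the list alone; camera adjusted p = 1.7e-13, and 0.031 with an estimated correlation). Among them the integrin Itgax rose from 5.80 ± 1.96 to 48.7 ± 32.1 CPM (3.07 ± 0.44, adjusted p = 0.0012), and S100a6 (1.85 ± 0.34, adjusted p = 0.0055). These counts depended on the STD KC libraries: 4 of the lipid-associated macrophage genes passed without std2 and 7 without std3, and of the monocyte-derived cell genes 4, 3 and 3 passed without std1, std2 and std3. The call of Gpnmb ended without std2 and without std3 (adjusted p = 0.13 and 0.11), and that of Trem2 without std1, std2 or std3 (0.058, 0.088 and 0.11).

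Of the 20 Kupffer cell identity genes 1 passed the test, Cd207, which fell (3 passed adjusted over the list alone, 1 up and 2 down; camera adjusted p = 0.0034 for lower, and adjusted p = 0.42 with an estimated correlation). The scavenger receptor Marco stood at 365 ± 88.7 CPM in STD KC and 1166 ± 722 in HFD KC (log2 fold change 1.67 ± 0.46, adjusted p = 0.056). Marco passed without HFD KC hfd2 (adjusted p = 0.032) and without HFD KC hf2 (0.028). The hemoglobin receptor Cd163 stood at 1524 ± 166 and 689 ± 357 CPM (-1.15 ± 0.37, adjusted p = 0.105), and it passed without HFD KC hf1 (0.032).

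Among further genes, the eosinophil chemokine receptor gene Ccr3 fell by 3.17 ± 0.39 on the log2 scale (adjusted p = 0.00036), the lectin Cd209f by 3.47 ± 0.65 (0.0063), and prostacyclin synthase, Ptgis, by 2.82 ± 0.45 (0.0026). The cytokine gene Il1b fell from 760 ± 172 to 195 ± 88.6 CPM (-1.96 ± 0.41, adjusted p = 0.013), a call that ended without std2 (0.068) and without std3 (0.079). Ccl9, a chemokine, rose by 3.13 ± 0.46 (adjusted p = 0.0015), and Tnip3, an inhibitor of NF-kappaB signalling, by 3.58 ± 0.46 (0.00038). Of the 12 LXR targets and cholesterol efflux genes 3 rose and none fell (4 adjusted over the list alone; camera adjusted p = 7.2e-05, and adjusted p = 0.071 with an estimated correlation). Only 1 passed without std1, without std2 or without std3. Abca1, the cholesterol exporter, rose from 146 ± 14.2 to 259 ± 37.8 CPM (0.83 ± 0.13, adjusted p = 0.0021). The lipase inhibitor Angptl4 rose by 2.10 ± 0.26 (adjusted p = 0.00036) and the lysosomal galactosidase Gla by 1.44 ± 0.22 (0.0017).

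Further lists passed the camera test in this comparison but not with an estimated correlation. Of 26 lysosome genes 4 rose (5 adjusted over the list alone; camera adjusted p = 3.4e-05, and adjusted p = 0.24 with an estimated correlation), and 2 passed without std1, std2, std3, HFD KC hfd2 or HFD KC hf2. Of 16 glycolysis genes 3 rose (10 adjusted over the list alone; camera adjusted p = 7.3e-05, and adjusted p = 0.24 with an estimated correlation), with 1 without std1, std2 or std3 and 5 without HFD KC hf1. Without Gapdh and Pgk1, chosen after their low levels were seen, 2 of 14 rose (camera adjusted p = 0.0010, and adjusted p = 0.28 with an estimated correlation). Of 22 matrix remodelling and growth factor genes 5 rose and 1 fell (12 adjusted over the list alone; camera adjusted p = 0.0032 for higher, and adjusted p = 0.13 with an estimated correlation), and 2, 1 and 1 rose without std1, std2 and std3. The member that fell did not pass without std2, std3 or HFD KC hfd2. Of 29 cell cycle genes 3 fell (6 adjusted over the list alone; camera adjusted p = 3.4e-05, and adjusted p = 0.52 with an estimated correlation), with 0 without std2 or std3 and 5 without HFD KC hfd2. Of 21 fatty acid oxidation genes 2 rose (2 adjusted over the list alone; camera adjusted p = 0.032, and adjusted p = 0.58 with an estimated correlation), and 1 passed without std2 or std3. Of 21 alternative activation and tissue-resident macrophage genes 3 fell and 1 rose (6 adjusted over the list alone; camera adjusted p = 0.022 for lower, and adjusted p = 0.34 with an estimated correlation). Without std2, std3 or HFD KC hfd2 1 fell, without std1, std2 or std3 0 rose, and without HFD KC hf1 2 rose. With only the frac_neg HFD KC libraries 3 of these lists did not pass: cell cycle (adjusted p = 0.95), fatty acid oxidation (0.11) and alternative activation (0.11). Lists that passed camera there but not with all 5 HFD KC libraries were erythroid (adjusted p = 2.8e-05 against 0.055), neutrophil (0.019 against 0.13) and hepatocyte markers (0.036 against 0.61), which were higher, and immediate early and dissociation stress genes (0.0050 against 0.34), which were lower. With all 5 libraries the camera test of hepatocyte markers pointed to lower. The mean log2 CPM of the cell cycle list was 3.85, 3.88 and 4.10 in the CD68 libraries hf1, hf2 and hf3 against 4.47 and 4.65 in the frac_neg libraries hfd1 and hfd2 and 4.37 to 4.58 in STD KC, so its fall followed the sort label or name prefix.

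Markers of other cells moved as well. Of 12 B and plasma cell markers 5 rose (10 adjusted over the list alone; camera adjusted p = 9.5e-10, and adjusted p = 0.16 with an estimated correlation). Of these, 3 passed without STD KC std1 or without HFD KC hf2, 2 without HFD KC hf3 and 0 without std2, without std3, with a term for the name prefix or with the 2 frac_neg HFD KC libraries alone. Ighm, the IgM heavy chain, stood at 52.2 ± 61.6 CPM in STD KC and 329 ± 95.9 in HFD KC. Of 17 T and NK cell markers 4 rose (12 adjusted over the list alone; camera adjusted p = 7.5e-10, and adjusted p = 0.24 with an estimated correlation). Of these markers 2 passed without std1, without std3 or without HFD KC hf3, 7 without HFD KC hf1 and 0 without std2. Of 12 dendritic cell markers 2 rose (3 adjusted over the list alone; camera adjusted p = 0.0034, and adjusted p = 0.34 with an estimated correlation), and 0 passed without std1 or std3 and 1 without std2. The 6 platelet markers were higher as a list (4 passed adjusted over the list alone; camera adjusted p = 0.020, and adjusted p = 0.42 with an estimated correlation). The 13 liver sinusoidal endothelial markers were lower as a list (camera adjusted p = 7.2e-05, and adjusted p = 0.42 with an estimated correlation). They varied within HFD KC, where Clec4g, chosen after its values were seen, ranged from 116 to 803 CPM against 505 to 839 CPM in STD KC.

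In all, 519 of 15285 genes passed an adjusted p under 0.05 in this comparison, 347 higher and 172 lower in HFD KC, and 331 of them changed at least 2-fold. The count fell to 291, 125 and 161 without STD KC std1, std2 and std3, and to 231 when only these 8 libraries entered the fit. It was 1162 by DESeq2, which shared 504 of the 519. The 3 CD68 libraries are also those named hf, so sort label and name prefix cannot be separated. The calls numbered 505 with the 2 frac_neg HFD KC libraries (327 shared) and 372 with the 3 CD68 libraries (290 shared).

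**Figure D2:**
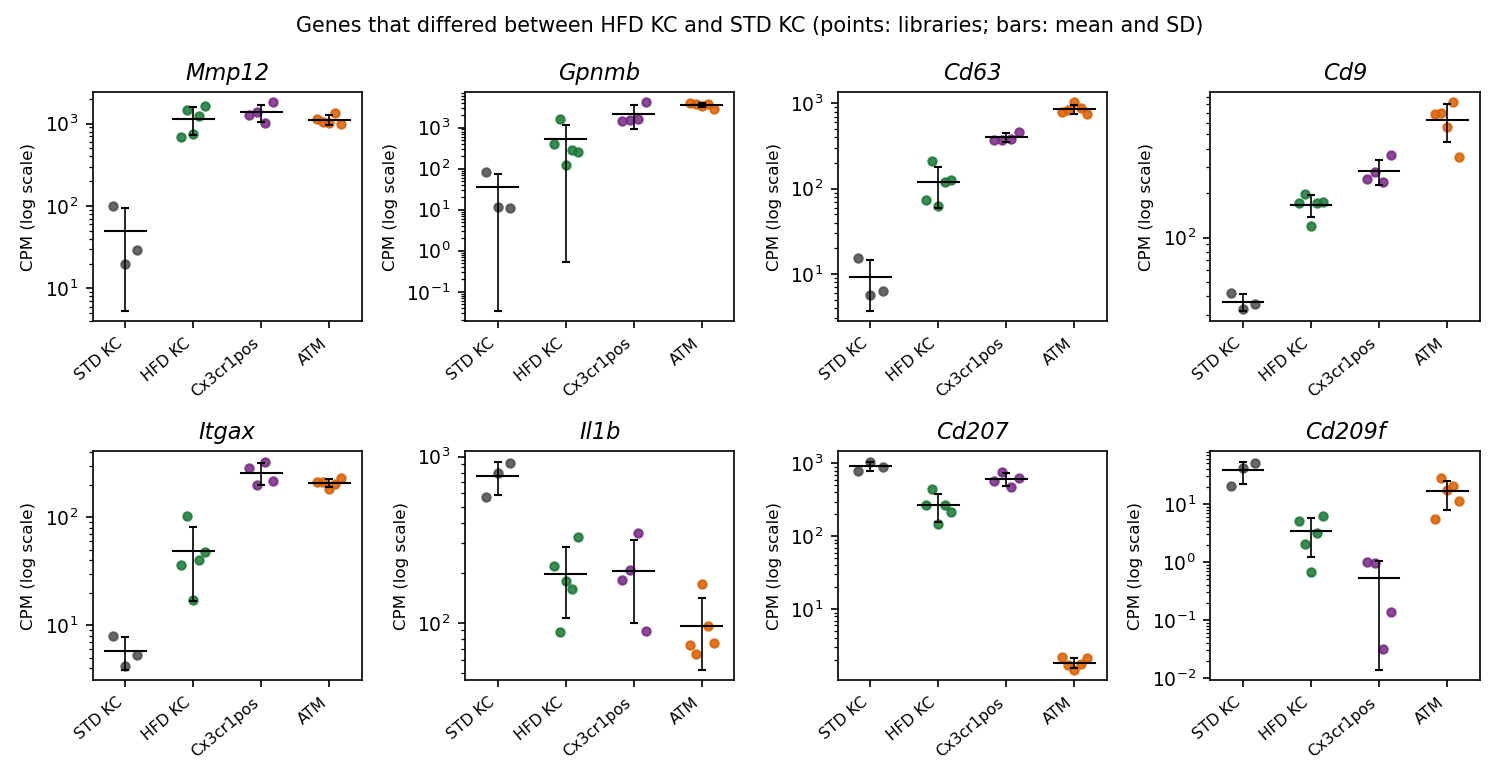
CPM on a log scale per library in the 4 groups for 8 genes that passed the test between HFD KC and STD KC (points are libraries, bars the mean and SD). Mmp12 averaged 49.9 CPM in STD KC and 1156 CPM in HFD KC, and Cd207 averaged 918 and 272 CPM.

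The second comparison set Cx3cr1pos HFD against HFD KC, the reporter-positive against the TIM4-positive liver macrophages of the HFD mice. Kupffer cell identity genes were lower in Cx3cr1pos HFD, and monocyte-derived cell genes and genes of MHC class II presentation were higher. Marco (ENSMUSG00000026390) fell from 1166 ± 722 to 31.0 ± 13 CPM (log2 fold change -5.23 ± 0.50 SE, adjusted p = 4.7e-06) and the complement component C6 (ENSMUSG00000022181) from 1160 ± 349 to 46.0 ± 25.1 CPM (-4.65 ± 0.35, adjusted p = 8.2e-07). Ccr2, the receptor that draws monocytes out of the marrow, rose from 30.1 ± 11.4 to 482 ± 196 CPM (4.00 ± 0.36, adjusted p = 2.9e-06). Cd74 (ENSMUSG00000024610), the invariant chain of MHC class II, rose from 19810 ± 6962 to 60852 ± 7996 CPM (1.62 ± 0.20, adjusted p = 4.6e-05).

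Of the 20 Kupffer cell identity genes 15 fell, 1 rose and 4 did not pass (18 passed adjusted over the list alone; camera adjusted p = 3.7e-27, and 0.0067 with an estimated correlation). The sort gene Timd4 is one of the 15. Cd163 fell by 4.49 ± 0.42 on the log2 scale and the folate receptor Folr2 by 2.76 ± 0.28. The 1 member that rose was Cd207, named after its values were seen, from 272 ± 113 to 608 ± 123 CPM (1.16 ± 0.23, adjusted p = 0.0028). Of 19 monocyte-derived cell genes 9 rose and none fell (9 adjusted over the list alone; camera adjusted p = 5e-13, and 0.020 with an estimated correlation), the sort gene Cx3cr1 among them. Ace, angiotensin-converting enzyme, rose by 3.95 ± 0.46 and the lectin Cd209a, which is also among the dendritic cell markers, by 3.12 ± 0.57. Of 22 lipid-associated macrophage genes 10 rose and 1 fell (11 adjusted over the list alone; camera adjusted p = 2.1e-05, and adjusted p = 0.24 with an estimated correlation). Trem2 rose from 197 ± 110 to 572 ± 133 CPM (1.54 ± 0.28, adjusted p = 0.0013), Cd63 from 119 ± 59.7 to 400 ± 43.6 CPM and osteopontin, Spp1, from 33.8 ± 43.3 to 416 ± 167 CPM (3.62 ± 0.79, adjusted p = 0.0055, and 4.82 without HFD KC hfd2). Mmp12, chosen after its values were seen, stood at 1156 ± 426 and 1376 ± 331 CPM and did not pass (adjusted p = 0.71).

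Of 11 MHC class II presentation genes 9 rose and none fell (11 adjusted over the list alone; camera adjusted p = 2e-14, and adjusted p = 0.062 with an estimated correlation). H2-Aa was up 1.80 ± 0.23 and H2-Ab1 1.86 ± 0.27 on the log2 scale. Of 17 complement genes 8 fell and 1 rose (12 adjusted over the list alone; camera adjusted p = 4.6e-12, and adjusted p = 0.068 with an estimated correlation). C2 fell by 4.29 ± 0.35, C4b by 3.90 ± 0.41 and properdin, Cfp, from 5200 ± 998 to 2030 ± 223 CPM (-1.36 ± 0.15). Of 18 iron and heme handling genes 7 fell and none rose (8 adjusted over the list alone; camera adjusted p = 2.9e-05, and adjusted p = 0.18 with an estimated correlation). Apoc1, an apolipoprotein, fell from 1209 ± 417 to 103 ± 70.6 CPM (-3.55 ± 0.38) and the growth factor gene Hbegf by 1.75 ± 0.20. Of 23 cholesterol synthesis genes 11 rose (14 adjusted over the list alone; camera adjusted p = 1.1e-05, and adjusted p = 0.20 with an estimated correlation). One was Sqle, squalene epoxidase (0.97 ± 0.22). That count was 5 without HFD KC hf1, 7 without HFD KC hf2 or hf3, 6 without Cx3cr1pos HFD hf1 or hfd2, and 2 with only libraries named hf. Of 29 cell cycle genes 6 rose (7 adjusted over the list alone; camera adjusted p = 4.3e-05, and adjusted p = 0.56 with an estimated correlation), and 3 passed without HFD KC hf1, hf2 or hf3 or without Cx3cr1pos HFD hf3 or hfd2. Of 22 matrix remodelling and growth factor genes 6 rose and 2 fell (13 adjusted over the list alone; camera adjusted p = 0.040 for higher, and adjusted p = 0.22 with an estimated correlation). Of 21 alternative activation and tissue-resident macrophage genes 4 fell and 1 rose (7 adjusted over the list alone; camera adjusted p = 0.020 for lower, and adjusted p = 0.33 with an estimated correlation), and 2 rose without HFD KC hf3. Of 22 interferon-stimulated genes 1 passed, Oasl1, which fell (-0.95 ± 0.18, adjusted p = 0.0017).

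Markers of other liver cells were lower in Cx3cr1pos HFD. Of 20 hepatocyte markers 11 fell (15 passed adjusted over the list alone; camera adjusted p = 3.8e-06, and adjusted p = 0.33 with an estimated correlation), and 5 fell with only libraries named hf. Albumin, Alb, stood at 104 ± 74.1 CPM in HFD KC and 24.9 ± 9.86 in Cx3cr1pos HFD. Of 13 liver sinusoidal endothelial markers 8 fell (13 adjusted over the list alone; camera adjusted p = 2e-05, and adjusted p = 0.38 with an estimated correlation). Stab2 was among them (-1.62 ± 0.24). This count was 2 with the replicate block that pairs libraries by name, 2 without HFD KC hfd1, HFD KC hf3, or Cx3cr1pos HFD hf1, hf3 or hfd2, and 4 without Cx3cr1pos HFD hf2. Of 6 erythroid markers 6 fell beside the iron and heme handling genes (6 adjusted over the list alone; camera adjusted p = 0.0027, and adjusted p = 0.37 with an estimated correlation). This count was 1 without HFD KC hfd1 or Cx3cr1pos HFD hf1 or hf2, 2 without HFD KC hfd2 or Cx3cr1pos HFD hfd2, and 3 without HFD KC hf3. Of 15 stellate cell and fibroblast markers 1 fell (1 adjusted over the list alone; camera adjusted p = 0.025, and adjusted p = 0.56 with an estimated correlation), and 2 fell without HFD KC hf1 or without Cx3cr1pos HFD hf2. With the replicate block this last list did not pass (adjusted p = 0.084), while T and NK cell markers (0.078 without and 0.041 with the block, higher) and LXR targets and cholesterol efflux genes (0.056 and 0.0496, lower) did. Cd79b, a B cell receptor gene, rose from 55.6 ± 17.1 to 141 ± 51.8 CPM (1.34 ± 0.27, adjusted p = 0.0028), 1 of 12 B and plasma cell markers to pass (camera adjusted p = 0.025 for the list, and adjusted p = 0.62 with an estimated correlation).

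In all, 2037 of 15285 genes passed, 894 higher and 1143 lower in Cx3cr1pos HFD, and 1138 changed at least 2-fold. The count was 1327 without Cx3cr1pos HFD hf3 and 1005 with only the 6 libraries named hf. The main fit took the libraries as independent, although those of HFD KC and Cx3cr1pos HFD that share a name deviated together. With the replicate block that pairs libraries by name the count was 1934, with 1652 shared.

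**Figure D3:**
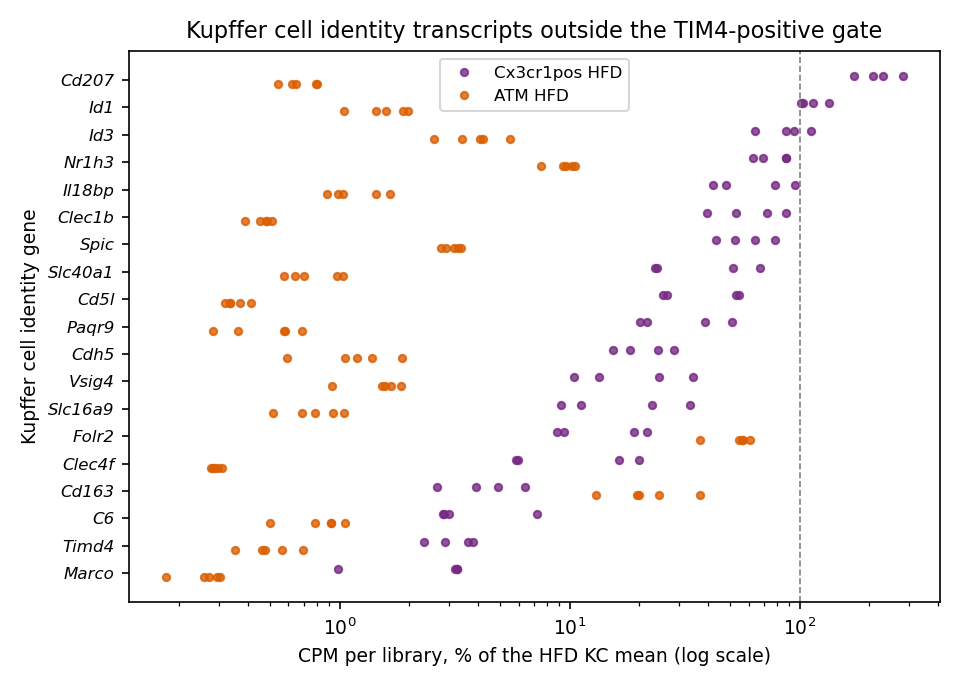
CPM of Kupffer cell identity genes in each Cx3cr1pos HFD and ATM HFD library as a percentage of the HFD KC mean, on a log scale, with a dashed line at 100%. Marco averaged 2.66% and Cd207 223% of HFD KC in the Cx3cr1pos libraries (Timd4 was a sort gene).

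The third comparison set ATM HFD against HFD KC, the macrophages of both tissues on the same diet. The Kupffer cell identity genes and the interferon-stimulated genes were lower in ATM without exception among the members tested. The lectin Clec4f (ENSMUSG00000014542) fell from 17626 ± 3689 to 51.1 ± 2.26 CPM (log2 fold change -8.43 ± 0.38 SE, adjusted p = 2.6e-11), and Irf7 (ENSMUSG00000025498), a transcription factor of the interferon response, from 1224 ± 72.2 to 57.2 ± 21.6 CPM (-4.42 ± 0.21, adjusted p = 5.9e-11). Retnla (ENSMUSG00000061100), a marker of alternative activation, rose from 4.99 ± 3.82 to 1082 ± 319 CPM (7.75 ± 0.53, adjusted p = 3.8e-09), and the lipid droplet gene Plin2 from 1149 ± 230 to 5180 ± 706 CPM (2.17 ± 0.14, adjusted p = 1.9e-09).

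All 20 Kupffer cell identity genes fell (20 adjusted over the list alone; camera adjusted p = 1.4e-59, and 0.00024 with an estimated correlation). Cd5l stood at 17565 ± 2558 CPM in HFD KC and 62.2 ± 6.71 in ATM and Clec1b at 981 ± 136 and 4.54 ± 0.447. All 22 interferon-stimulated genes fell (22 adjusted over the list alone; median log2 fold change -2.09; camera adjusted p = 1.8e-23, and 0.034 with an estimated correlation). Oas3 fell by 3.52 ± 0.24, Usp18 by 2.69 ± 0.18 and Bst2 by 1.98 ± 0.12. Of 12 LXR targets and cholesterol efflux genes 10 fell and none rose (10 adjusted over the list alone; camera adjusted p = 5.2e-06, and 0.034 with an estimated correlation). Apoc1 stood at 1209 ± 417 and 4.00 ± 0.487 CPM, and the desaturases Scd1 and Scd2 changed by -4.16 ± 0.37 and -3.12 ± 0.20. Of 23 cholesterol synthesis genes 18 rose and none fell (19 adjusted over the list alone; camera adjusted p = 5e-05, and adjusted p = 0.25 with an estimated correlation). Hmgcs1 rose by 1.20 ± 0.11 and Msmo1 by 1.35 ± 0.14.

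Of 22 lipid-associated macrophage genes 16 rose and 2 fell (18 adjusted over the list alone; camera adjusted p = 1.4e-05, and adjusted p = 0.24 with an estimated correlation). Lgals1 rose from 34.7 ± 18.8 to 1078 ± 119 CPM, while Acp5, an acid phosphatase, fell from 1519 ± 285 to 143 ± 10.3 CPM, and Mmp12, at 1156 ± 426 and 1116 ± 145 CPM, did not pass (adjusted p = 0.92). Of 19 monocyte-derived cell genes 13 rose and 4 fell (18 adjusted over the list alone; camera adjusted p = 0.020, and adjusted p = 0.45 with an estimated correlation). S100a4 rose by 5.93 ± 0.27 and fibronectin, Fn1, by 5.88 ± 0.41, while Treml4 fell from 1200 ± 216 to 7.04 ± 1.64 CPM. Of 29 cell cycle genes 25 rose and 1 fell (26 adjusted over the list alone; camera adjusted p = 3e-05, and adjusted p = 0.53 with an estimated correlation). Pcna rose by 0.97 ± 0.07 and Birc5 by 1.31 ± 0.15. Of 17 complement genes 11 fell and 3 rose (14 adjusted over the list alone; camera adjusted p = 5.3e-05, and adjusted p = 0.28 with an estimated correlation). Of 18 iron and heme handling genes 10 fell and 4 rose (14 adjusted over the list alone; camera adjusted p = 0.030, and adjusted p = 0.53 with an estimated correlation). The iron exporter Slc40a1 fell from 11349 ± 2913 to 89.2 ± 23.7 CPM. Of 19 immediate early and dissociation stress genes 11 rose and 2 fell (13 adjusted over the list alone; camera adjusted p = 0.008, and adjusted p = 0.53 with an estimated correlation). Egr2 rose by 2.78 ± 0.30. The cytokine Il1a fell from 162 ± 32.7 to 4.12 ± 1.13 CPM, and the chemokine Ccl8 rose from 8.25 ± 5.20 to 333 ± 149 CPM. Cpe, a peptide processing enzyme, stood at 0.189 ± 0.105 CPM in HFD KC and 109 ± 17.3 in ATM.

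All 20 hepatocyte markers and all 13 liver sinusoidal endothelial markers fell (camera adjusted p = 5.5e-19 and 1.7e-12, and adjusted p = 0.093 and 0.22 with an estimated correlation). Of 6 erythroid markers 6 fell as well (6 adjusted over the list alone; camera adjusted p = 0.033, and adjusted p = 0.57 with an estimated correlation). Of 15 stellate cell and fibroblast markers 9 rose and 4 fell, decorin, Dcn, from 22.2 ± 6.52 to 98.0 ± 28.5 CPM, and of 9 adipocyte markers 5 rose and 2 fell, although adiponectin, Adipoq, reached only 1.14 ± 0.515 CPM in ATM. Neither list passed the camera test (adjusted p = 0.14 and 0.20). In all, 7496 of 15285 genes passed, 3642 higher and 3854 lower in ATM (4249 and 3389 with total counts, 4320 and 3933 by DESeq2, 3826 and 3721 with RLE factors), and 4351 changed at least 2-fold. Tissue, isolation and sort gate differ together in this comparison, so the values describe the sorted cells as prepared.

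Both HFD comparisons against HFD KC called 626 genes up and 872 genes down in common, and 117 in opposite directions. Independent lists of the same sizes would share 213 and 288 genes, and with the 5 HFD KC libraries split between the comparisons a median of 207.5 genes were up and 409 down in both, against 51.9 and 95.4 for independent lists.

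The fourth comparison set ATM HFD against Cx3cr1pos HFD, the adipose against the reporter-positive liver macrophages. Tissue, isolation and sort gate differ together here too, and the sort label is frac_neg for ATM and frac_pos for Cx3cr1pos. Of the 20 Kupffer cell identity genes 18 fell and 2 rose (20 adjusted over the list alone; camera adjusted p = 2.6e-48, and 0.00045 with an estimated correlation). Cd207 (ENSMUSG00000034783) fell from 608 ± 123 to 1.85 ± 0.306 CPM (log2 fold change -8.35 ± 0.31 SE, adjusted p = 3.2e-12) and Cd5l from 6984 ± 2792 to 62.2 ± 6.71 CPM (-6.81 ± 0.25, adjusted p = 2.6e-12). The 2 that rose, named after their values were seen, were Folr2, from 166 ± 74.0 to 594 ± 105 CPM (1.84 ± 0.27, adjusted p = 3.9e-05), and Cd163, from 30.7 ± 10.9 to 157 ± 60.8 CPM (2.35 ± 0.38, adjusted p = 0.00011).

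All 22 interferon-stimulated genes fell against this liver group too (22 adjusted over the list alone; median log2 fold change -1.99; camera adjusted p = 1.6e-31, and 0.021 with an estimated correlation). Irf7 fell by 3.88 ± 0.21 and Oas3 by 3.82 ± 0.25. Of 12 LXR targets and cholesterol efflux genes 9 fell and 1 rose (10 adjusted over the list alone; camera adjusted p = 8.3e-06, and 0.036 with an estimated correlation), with Fasn, fatty acid synthase, lower by -1.60 ± 0.15 and Scd2 by -2.95 ± 0.20. Of 22 lipid-associated macrophage genes 14 rose and 2 fell (16 adjusted over the list alone; camera adjusted p = 0.0081, and adjusted p = 0.51 with an estimated correlation), Plin2 by 1.55 ± 0.15. Of 21 alternative activation and tissue-resident macrophage genes 12 rose and 4 fell (16 adjusted over the list alone; camera adjusted p = 0.017, and adjusted p = 0.45 with an estimated correlation). Retnla rose by 8.47 ± 0.61 and the lectin Clec10a by 4.14 ± 0.20, while the transglutaminase Tgm2 fell from 578 ± 53.2 to 45.6 ± 11 CPM. Of 11 MHC class II presentation genes 5 fell and none rose (6 adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.58 with an estimated correlation), H2-DMb2 by 2.39 ± 0.31.

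Of 16 glycolysis genes 10 fell and 1 rose (12 adjusted over the list alone; camera adjusted p = 0.0081, and adjusted p = 0.51 with an estimated correlation), and 6 fell without ATM HFD hfd2. Without Gapdh and Pgk1 9 of 14 fell and 1 rose (camera adjusted p = 0.0084, and adjusted p = 0.46 with an estimated correlation). Hexokinase 2, Hk2, fell from 114 ± 7.95 to 17.7 ± 2.89 CPM. Of 21 fatty acid oxidation genes 10 rose and 2 fell (12 adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.55 with an estimated correlation), Acadm by 0.77 ± 0.11. Of 29 cell cycle genes 9 rose and 2 fell (12 adjusted over the list alone; camera adjusted p = 0.017, and adjusted p = 0.71 with an estimated correlation), and 20 rose without Cx3cr1pos HFD hfd2 and 5 without Cx3cr1pos HFD hf3. Of 23 cholesterol synthesis genes 9 rose and none fell (9 adjusted over the list alone; camera adjusted p = 0.033, and adjusted p = 0.55 with an estimated correlation), and 5 rose without Cx3cr1pos HFD hf3. Of 19 immediate early and dissociation stress genes 6 rose and none fell (6 adjusted over the list alone; camera adjusted p = 0.029, and adjusted p = 0.62 with an estimated correlation). The metalloprotease genes Mmp14 and Mmp13 fell by 4.14 ± 0.35 and 4.02 ± 0.56, and the inhibitor Timp2 rose by 2.54 ± 0.26.

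Of 20 hepatocyte markers 19 fell and all 13 liver sinusoidal endothelial markers fell (camera adjusted p = 1.1e-19 and 3.9e-12, and adjusted p = 0.067 and 0.20 with an estimated correlation). Of 15 stellate cell and fibroblast markers 10 rose and 4 fell (camera adjusted p = 0.0070, and adjusted p = 0.51 with an estimated correlation), Dcn by 2.54 ± 0.24. Of 12 B and plasma cell markers 8 fell and of 17 T and NK cell markers 8 fell (camera adjusted p = 0.010 and 0.033, and adjusted p = 0.55 and 0.71 with an estimated correlation). Of 12 dendritic cell markers, beside the MHC class II presentation genes, 6 fell (7 adjusted over the list alone; camera adjusted p = 0.049, and adjusted p = 0.55 with an estimated correlation). In all, 6073 of 15285 genes passed, 2893 higher and 3180 lower in ATM (3503 and 2575 with total counts, 3575 and 3046 by DESeq2, 3151 and 2878 with RLE factors), and 3512 changed at least 2-fold.

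**Figure D4:**
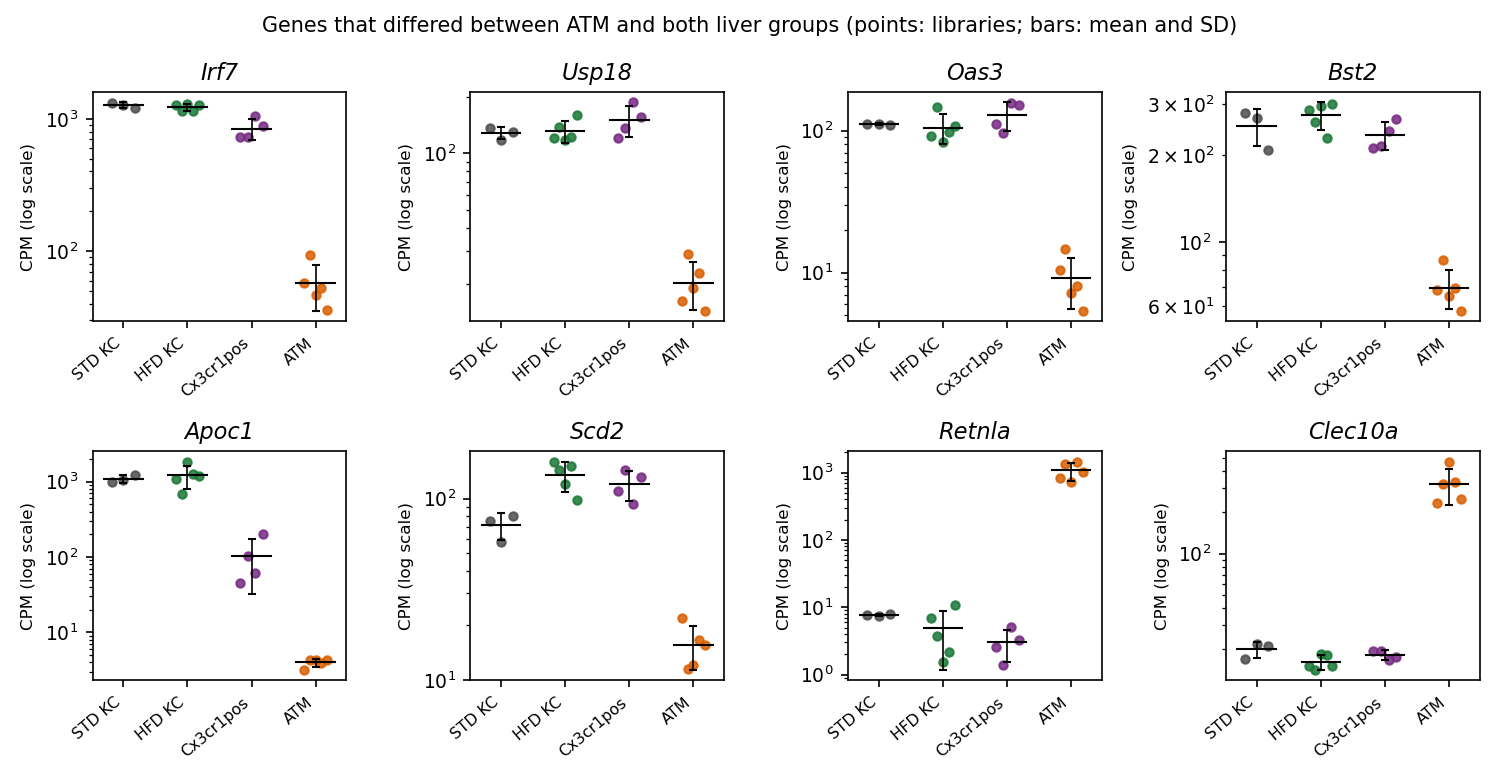
CPM on a log scale per library in the 4 groups for 8 genes that passed the test between ATM HFD and both liver groups of the HFD (points are libraries, bars the mean and SD). Irf7 averaged 57.2 CPM in ATM against 1224 CPM in HFD KC and 843 CPM in Cx3cr1pos HFD, and Retnla 1082 CPM against 4.99 and 3.06 CPM.

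**Figure D5:**
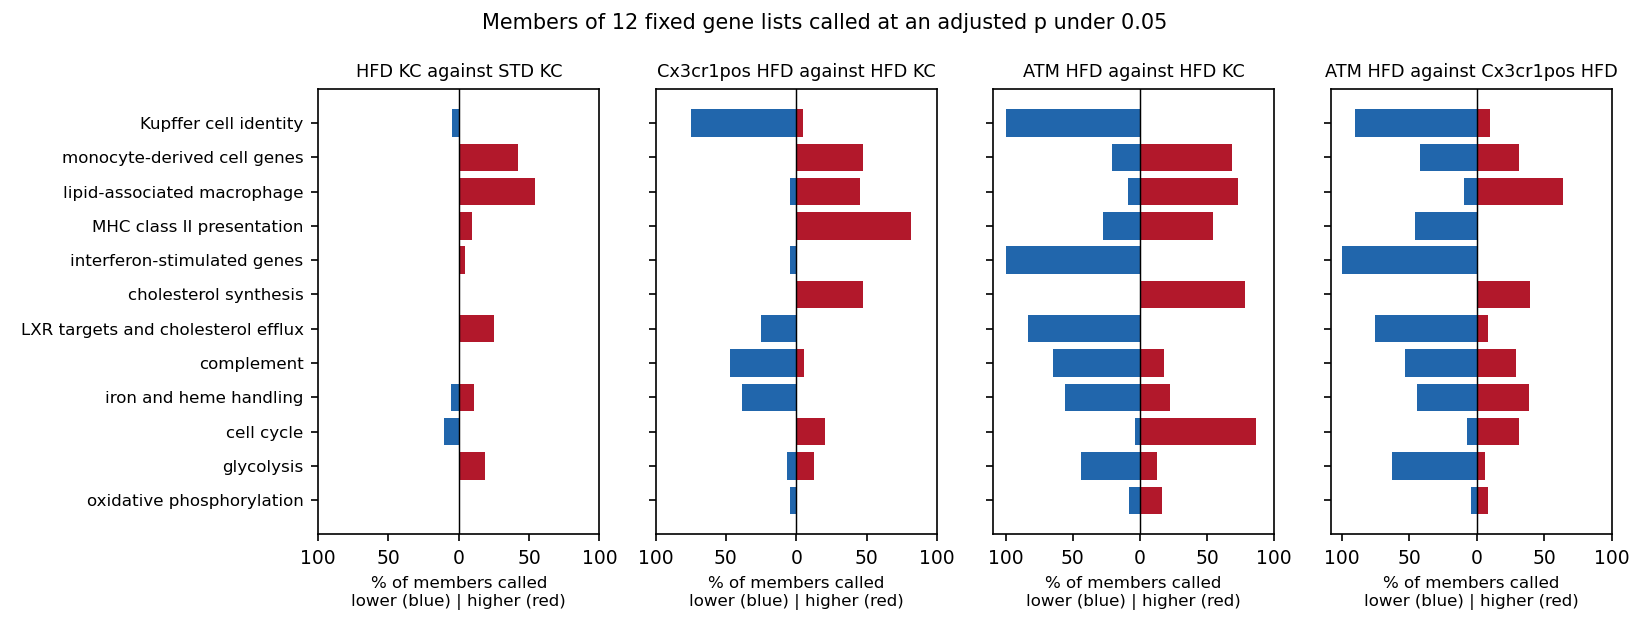
Percentage of the tested members of 12 gene lists called lower (blue, to the left) and higher (red, to the right) at an adjusted p under 0.05 in each of the 4 comparisons. All 22 interferon-stimulated genes were lower in ATM against either liver group, and 12 of 22 lipid-associated macrophage genes were higher in HFD KC than in STD KC.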

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

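Of the tests in this part, the list medians with only frac_neg libraries, the share that other Cx3cr1pos transcripts reach and the comparison of interferon-stimulated genes between the liver groups were chosen only after the results were seen. The scaling test of interferon-stimulated genes also used total counts, a setting added after seeing the data. In 253 tests for a library far from the rest of its group, 21 stood out, and 7 of the 21 were in Cx3cr1pos HFD hfd2. Chance gives about 1 in 20, or 13, for independent tests. These tests covered genes named in the text and library measures, which can vary together within a library, so 13 is only a rough guide. STD KC, with 3 libraries, was too small for these tests, so none of its libraries could stand out.

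In Cx3cr1pos HFD hfd2 the level of Gpnmb was 4106.55 CPM (1446.4 to 1647.56 in the other libraries of its group), of Trem2 768.409 (479.566 to 526.331), of Cd63 464.729 (372.574 to 387.225), of Ccl9 446.381 (249.968 to 279.316), of C6 83.6114 (32.7302 to 34.7516), of C4b 70.9493 (22.6088 to 28.586) and of Birc5 26.6496 (19.1721 to 19.7692). In HFD KC hfd2 Gpnmb stood at 1586.01 CPM (124.2 to 389.573 in the others), Ccl9 at 261.7 (79.4706 to 112.346) and Spp1 at 110.824 (10.0389 to 21.7009). In HFD KC hfd1 Adgre1 stood at 7017.95 CPM (4089.35 to 4717.24 in the others) and Alb at 232.45 (43.5524 to 91.1514), and in HFD KC hf2 Clec1b stood at 1217.55 (880.252 to 972.58) and Ptgis at 19.1405 (4.4283 to 8.11734).

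Ighm was at 1442.96 CPM in Cx3cr1pos HFD hf1 (483.169 to 539.131 in the others) and Marco at 11.4667 in Cx3cr1pos HFD hf2 (36.8699 to 37.8085). In ATM HFD, Ccl9 was at 2428.2 CPM in hf1 (924.02 to 1313.27 in the others), Folr2 at 411.972 in hf3 (608.755 to 681.039) and Hbegf at 17.3017 in hfd2 (12.5906 to 12.9466). The 10 most abundant genes took 20.3805% of the counts in Cx3cr1pos HFD hf3 (19.5913 to 19.6749% in the others) and 17.9305% in ATM HFD hf2 (16.6383 to 16.9247%).

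Lipid-associated macrophage and monocyte-derived cell genes were higher in HFD KC than in STD KC. The sort label alone is argued against by the 2 frac_neg HFD KC libraries, since STD KC is labelled frac_neg as well. With these the median log2 fold change over all tested members was 1.71 for the lipid-associated and 1.87 for the monocyte-derived list (camera adjusted p = 1.9e-30 and 5.5e-19). The name prefix cannot be judged this way, since these 2 libraries are named hfd and all STD KC libraries std, so prefix and diet coincide. The planned test of Cx3cr1pos cells mixed into the HFD KC libraries came out open: the share of such RNA that the called members need exceeded the share that the fall of Kupffer cell identity genes allows in 4 of 5 libraries, by 10.3 ± 9.19 percentage points, short of the 5 libraries and 2 SD set beforehand. An added test was then dropped, since its choice of genes fixed its result. The next took 83 transcripts at least 8 times higher in Cx3cr1pos HFD than in STD KC, chosen without HFD KC and without the sort genes (9 of them called members). Their median share fell short of the needed one in 5 of 5 libraries, by 17.3 ± 7.54 points. The called members were chosen as higher in HFD KC, which can raise the needed share. For all 30 listed genes at least 2 times higher in Cx3cr1pos HFD, chosen without HFD KC, the gap was 14.5 ± 6.32 points. Both gaps exceeded 2 SD only narrowly. They argue against RNA of average Cx3cr1pos cells as the whole cause, without excluding it. A change of Kupffer cells with the diet may underlie the rest. A mixed share near that of the 83 transcripts (13.8% in hfd1, 27.6% in hfd2, the library closest to a Cx3cr1pos library, 4.15% in hf1, 12% in hf2 and 16.8% in hf3), a subset of Cx3cr1pos cells and TIM4-positive cells that lack Cx3cr1 stay open. The sort for TIM4 would remove TIM4-negative cells such as recent monocyte-derived Kupffer cells, though Timd4 RNA was lowest in hfd2.

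Kupffer cell identity transcripts were present in Cx3cr1pos libraries at unequal levels. Kupffer cells mixed into the Cx3cr1pos libraries would keep these genes in 1 ratio only if they were the sole source of these transcripts. The ratios to HFD KC spanned 65.3 to 286-fold within the 4 libraries. Cd207 was the highest in each, and C6 (hf1), Marco (hf2 and hfd2) or Cd163 (hf3) the lowest. Cd207 was already called higher in Cx3cr1pos HFD, so its ratio was bound to part from the rest. The span argues only against mixed Kupffer cells as the sole source, and cannot decide on a partial share. As means over the libraries, Marco stood at 2.66%, Cd5l at 39.8% and Cd207 at 223% of HFD KC. Reporter-positive cells that express part of the Kupffer cell program are a candidate explanation, and a smaller share of mixed Kupffer cells stays open.

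Interferon-stimulated genes were lower in ATM than in both liver groups. Scaling between libraries is argued against by a median log2 fold change of -1.90 or lower with RLE factors or total counts, and the name prefix by -2.03 or lower with only libraries named hf. Hepatocytes and endothelial cells in the liver libraries are argued against by a median of 0.0145 between Cx3cr1pos HFD and HFD KC, where their markers fell. Lymphoid and dendritic cells are not covered, since their marker lists did not fall there. B and plasma, T and NK and dendritic cell markers were lower in ATM HFD than in Cx3cr1pos HFD (camera adjusted p = 0.010, 0.033 and 0.049, and 0.55, 0.71 and 0.55 with an estimated correlation). Between ATM HFD and HFD KC none of these lists passed camera. A difference between the tissues may underlie the pattern, but isolation and sort gate differ with the tissue and were not tested.

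Other splits of the libraries were set beside the counts of genes. They argue against chance in the comparisons that hold Cx3cr1pos HFD or ATM HFD. For HFD KC against STD KC they cannot decide, since a split that does not follow the diet called as many genes. The 231 genes called between HFD KC and STD KC in a fit of these groups alone were matched by 2 of 56 splits, the real one included, and the highest other gave 231 as well: it set hfd2, hf1 and hf2 apart, the libraries low in sinusoidal endothelial markers. For Cx3cr1pos HFD against HFD KC 1 of 100 splits, the real one, reached 1475 (highest other 1, and 0 among the 12 that parted as many name pairs), and for ATM HFD against HFD KC 1 of 100 reached 6373 (highest other 1). For ATM HFD against Cx3cr1pos HFD 1 of 100 reached 5205, and the highest other, 2020, moved a single ATM library, a structure of the samples by tissue.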

How the results depend on the processing

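Total counts in place of TMM, the list member counts and the shortened glycolysis list were chosen only after the results were seen. The 519 genes between HFD KC and STD KC became 1162 by DESeq2 and 231 with only these groups in the fit, and 125 to 545 without single libraries (291, 125 and 161 without std1, std2 and std3, where fewer controls remain). The 2037 between Cx3cr1pos HFD and HFD KC became 1005 with only libraries named hf, which are fewer, and 1327 to 2114 without single libraries, the lowest without Cx3cr1pos HFD hf3. The 7496 and 6073 of the ATM comparisons stayed within 1.5 times, at 6864 to 7315 and 5246 to 6090 without single libraries. With an estimated correlation the passing lists numbered 2, 2, 3 and 3 in place of 15, 15, 13 and 17, and by fry, which tests another hypothesis, 8 for HFD KC against STD KC and 22 for ATM HFD against HFD KC. The overlap of 1498 genes became 843 at a log2 fold change of at least 1, and 623.5 with the HFD KC libraries split, where each fit holds fewer. The cause was not tested for the other shifts.

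With the replicate block that pairs libraries by name, the counts were 1934 (1652 shared), 7611 and 5994, but names paired the ATM libraries only in part. For HFD KC with ATM the correlations were -0.0196 to 0.186, and those of hf2 and hf3 did not exceed that with every other name. For Cx3cr1pos with ATM they were 0.0465 to 0.204, and those of hf1 and hfd2 did not. By DESeq2 the median log2 fold change of all genes was 0.136 and 0.122 in the ATM comparisons. Total counts moved the share of higher genes among those called from 48.6 to 55.6% between ATM HFD and HFD KC and from 47.6 to 57.6% between ATM HFD and Cx3cr1pos HFD. Of the named genes under the alternatives, 1985 values kept their direction and side of the threshold, 35 lost the call, 10 gained one and none reversed. Genes were named with preference for calls that held without any single library, and leaving out each library is among these alternatives. The counts for named genes therefore cannot show how stable the calls of all genes were. At the depth of these libraries a gene without counts can lie anywhere below the level that 3 counts give.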

Other observations

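The sums of marker levels per library were chosen only after the results were seen, while the lists and their camera tests were fixed beforehand. Liver sinusoidal endothelial markers, 13 genes of the cells that line the vessels Kupffer cells sit in, varied among the HFD KC libraries. Their summed level was 7370 CPM in hfd1 and 7351 in hf3 against 3431 in hfd2, 2064 in hf2 and 1959 in hf1, while the STD KC libraries held 7393 to 10251 and the Cx3cr1pos HFD libraries 1397 to 2356. Hepatocyte markers summed to 861 CPM in HFD KC hfd1 and 186 to 418 in the other HFD KC libraries.

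Lists of energy metabolism did not pass the camera test between ATM HFD and HFD KC, where 7496 of 15285 genes passed one by one, and the lists were not compared with each other. Of 24 oxidative phosphorylation genes 4 rose and 2 fell, with a median log2 fold change of -0.01 and a camera test pointing up (adjusted p = 0.95, and 0.99 with an estimated correlation). Without HFD KC hf1 7 of these rose, and without ATM HFD hfd2 1 fell. Of 21 fatty acid oxidation genes 9 rose and 6 fell (camera adjusted p = 0.20, and 0.72 with an estimated correlation), and of 16 glycolysis genes 2 rose and 7 fell (camera adjusted p = 0.14, and 0.68 with an estimated correlation; 2 and 7 of 14 without Gapdh and Pgk1, adjusted p = 0.12 and 0.60). Of 22 inflammatory cytokine and chemokine genes 10 rose and 6 fell between ATM HFD and HFD KC, where the median log2 fold change was 0.22 and the camera test pointed down (adjusted p = 0.98, and 0.99 with an estimated correlation).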
